A study of Mus musculus with 10 samples.

How the data were processed

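Gene expression was measured on 10 Affymetrix arrays of biotin-labelled RNA from primary mouse embryonic fibroblasts (MEFs). According to the sample labels, 3 arrays were of wild type cells, 3 of Snf5-/- cells and 4 of Brg1-/- cells. The labels state that the cells came from embryos at day 13.5 on a mixed C57BL/6 and 129 background, that Cre recombinase was delivered by retrovirus, and that infected cells were selected with puromycin at 2.5 ug/ml. The deposited values are MAS5 probe set intensity on a linear scale, as named in the submitters' processing notes. The MAS5 version, its scaling target and any filters were not given in the sources used here. The deposited intensity table holds 22690 probe sets, with 0 missing values, 0 values at or below 0 and 0 pairs of identical arrays. The number of arrays limits the precision of every value.

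The deposited intensities of the 10 arrays did not share a common level. Median intensity ranged from 146 to 234, and the mean after trimming 2% from each end ranged from 414 to 780. As planned for the case in which array medians differ by over 0.5 on the log2 scale, quantile-normalized values (limma, normalizeQuantiles) were computed beside the deposited log2 values, and both are given throughout. Counts of changed genes come first from the deposited scale. Log2 changes of single genes are given on the quantile-normalized scale, with the standard error (SE) of the fit. A gene written as having risen, fallen or changed passed the threshold on both scales unless the text states otherwise.

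Probe sets were assigned to genes with the annotation supplied for this array. A single gene symbol was carried by 20380 probe sets other than controls. A further 691 carried several symbols and 1606 were not listed, and controls were not taken out of these counts. The 64 control probe sets, and probe sets with no symbol or several symbols, were left out of gene counts. For a gene with several probe sets, the probe set with the highest mean log2 value over the 10 arrays stood for the gene. Probe sets at or above the 40th percentile of their array in at least 3 arrays were kept, which left 8398 genes. Log2 values were taken with no pseudocount. The annotation of gene positions was on mouse assembly GRCm38.

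Each gene was fitted with limma 3.58.1 (R 4.3.3) with a mean for each of the 3 groups, which gave 7 residual degrees of freedom, and eBayes with an intensity trend. A total of 3 comparisons were made, namely Snf5-/- against wild type, Brg1-/- against wild type and Brg1-/- against Snf5-/-. Tests were two-sided, and p-values were adjusted by the Benjamini-Hochberg method within a comparison, with a threshold of 0.05. The overlap of both mutants was set beside the product expected of independent lists, and beside 100 simulated data sets of unchanged groups that share their wild type arrays. These simulations drew every gene independently, with no deviation common to many genes of an array. The labels do not state whether the replicates of a genotype came from separate embryos or cultures, so the p-values measure the spread between these arrays only.

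Gene lists for pathways, complexes, cell cycle phases and other cell types were tested with the limma function camera at its preset inter-gene correlation of 0.01, which compares the genes of a list with all other genes. Of 34 lists, with 842 genes of which 736 were on the array, 32 had at least 5 measured genes and were tested. Adjustment ran over the lists within a comparison. Camera with a correlation estimated for each list, and the limma function fry in its directional form, were run as alternatives. For each list, members past the threshold were counted with adjustment over all genes and also adjusted over the list alone. An SE over genes gives the spread among the genes of a list, which are not independent, and not the spread between arrays.

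Genes named in the text were chosen by rule. They are Smarcb1, Smarca4 and Smarca2, the 10 largest rises and the 10 largest falls against wild type among genes past the threshold whose arrays did not overlap between the groups, and up to 4 members with the smallest adjusted p of each described list. For the pair of mutants they are the 5 genes of largest change in each direction shared by both, up to 6 genes past the threshold in opposite directions, and the 5 largest differences in each direction between the mutants. Predicted genes without a name were passed over. These choices, the model, the filter, the gene lists and most alternatives were made before the data were examined. A background level for each array, the highest of 27 Bacillus subtilis control probe sets, was chosen after the data were examined. It ranged from 26.7 to 57.4. Where every array of a group lay at or below it, the change is given as at least the fold between the other group and the background.

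RNA quality was checked with the ratio of 3-prime to 5-prime control probe sets of Gapdh and beta-actin, and hybridization with 9 spiked bacterial and phage control probe sets. Differences between groups in array measures were tested by exact permutation over all splits of the arrays, two-sided, with adjustment over 15 tests.

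The procedure was tested on simulated data in which 200 of 8398 genes were changed. At a log2 change of 1, 74% of the changed genes were recovered for each mutant against wild type and 56% for the mutants against each other. At a log2 change of 0.5, recovery was 12% for the Snf5-/- layout, 6% for the Brg1-/- layout and 4% for the mutants against each other. False calls made up 4.79% of all calls for the Snf5-/- layout, 2.14% for the Brg1-/- layout and 2.34% for the direct comparison. The simulated arrays used the spread of the deposited scale and drew every gene independently. They held no shift common to many genes of an array, so these rates leave out calls that come from differences in array brightness.

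The alternatives chosen before the data were examined were quantile normalization, centring of arrays on their median, pseudocounts of 16 and 64, no filter, a filter at the 60th percentile, the mean of a gene's probe sets, removal of probe sets that may detect several transcripts, moderation without an intensity trend or with robust moderation, array weights, the replicate number as a block, leaving out each array, fitting only the groups compared, a threshold of 0.01, an added 2-fold minimum, all probe sets in place of genes, and both other list tests. Cyclic loess, scaling to the hybridization controls and a repeat of list counts without Snf5-/- replicate 2 on the quantile-normalized scale were added after the data were examined. Figures were drawn with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. Data on nucleosome occupancy were not used here.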

Results

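The series concerns SWI/SNF, a chromatin remodelling complex that moves nucleosomes and acts as a tumour suppressor, and this part of it asks how gene expression in fibroblasts differs when a subunit of the complex is lost. Snf5 (gene Smarcb1) is a core subunit and Brg1 (gene Smarca4) is an ATPase subunit that drives the remodelling. Expression was profiled on 3 arrays of wild type MEFs, 3 arrays of Snf5-/- MEFs and 4 arrays of Brg1-/- MEFs, and 8398 genes were tested. MEFs are connective tissue cells grown from mid-gestation embryos.

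The wild type arrays were the brightest on the deposited scale. Mean array median intensity was 208 ± 22.6 (SD, n = 3) in wild type, 173 ± 14.3 (n = 3) in Snf5-/- and 156 ± 12.1 (n = 4) in Brg1-/-. The median log2 change over all tested genes was -0.27 in Snf5-/- and -0.47 in Brg1-/- on the deposited scale, and 0.02 in both after quantile normalization, so changes of single genes are given relative to the array as a whole, on the quantile-normalized scale. Array medians differed between Brg1-/- and wild type with an exact permutation p = 0.0286, the smallest that 35 splits allow, and an adjusted p of 0.214. Between Snf5-/- and wild type the exact permutation p was 0.1, the smallest that 20 splits allow. The spiked hybridization controls differed by -0.03 (log2) between Brg1-/- and wild type, with exact permutation p = 0.714. The beta-actin ratio of 3-prime to 5-prime signal differed by -0.03 (log2, exact permutation p = 0.343) for Brg1-/- and 0.01 (p = 0.6) for Snf5-/-, and that of Gapdh by 0.09 (p = 0.0571) and 0.17 (p = 0.2).

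**Figure D1:**
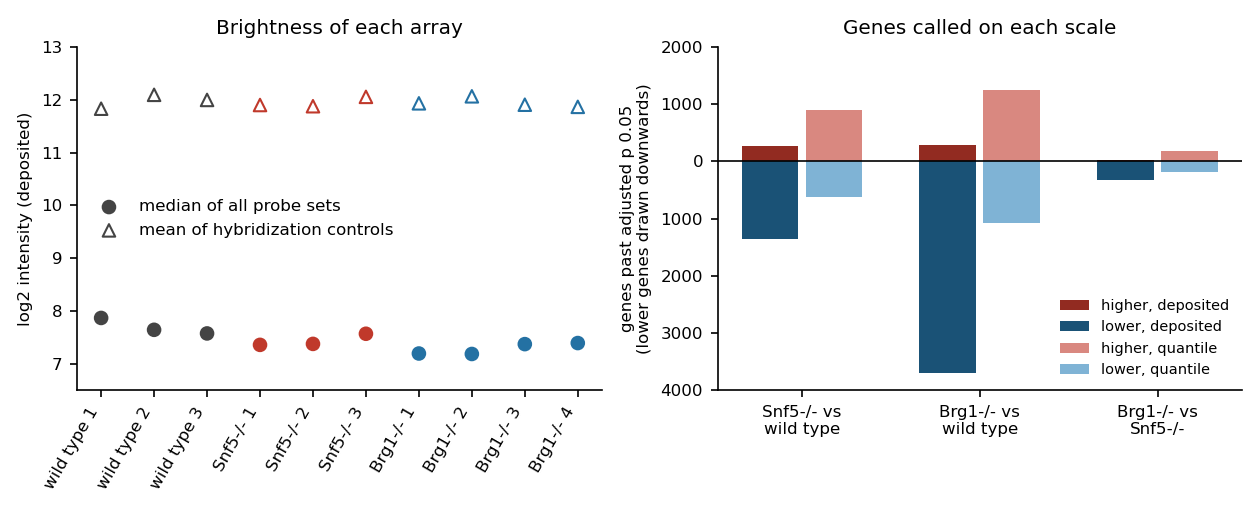
Left, the median log2 intensity of all probe sets (filled points) and the mean of the hybridization controls (open triangles) in each array on the deposited scale. Right, genes past adjusted p 0.05 in the 3 comparisons, higher genes drawn upwards and lower genes downwards, on the deposited and quantile-normalized scales. In Brg1-/- against wild type, 92.8% of called genes were lower on the deposited scale and 46.4% on the quantile-normalized scale.

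The targeted transcripts were low in the genotypes named for them. Smarcb1 (chromosome 10, 75896769 to 75921614, mouse assembly GRCm38) measured 951 ± 147 (SD, n = 3) intensity units in wild type, 297 ± 29.8 (n = 3) in Snf5-/- and 899 ± 103 (n = 4) in Brg1-/-. In Snf5-/- it fell by 1.37 ± 0.11 (SE, log2), with adjusted p = 1.98e-05. Its values in the single arrays were 1119, 844 and 891 in wild type, 280, 279 and 331 in Snf5-/-, and 808, 826, 932 and 1030.1 in Brg1-/-. A second, dimmer Smarcb1 probe set measured 138 ± 93.3 in wild type and 56.7 ± 32.9 in Snf5-/-, and its change of -0.96 ± 0.48 did not pass (adjusted p = 0.201, or 0.0765 on the deposited scale). Smarca4 (chromosome 9, 21616106 to 21704230) measured 2849 ± 853 in wild type, 2807 ± 370.0 in Snf5-/- and 450.4 ± 105 in Brg1-/-. It fell by 2.10 ± 0.14 in Brg1-/- (adjusted p = 2.25e-06), with 3829, 2443 and 2275 in the wild type arrays, 2833, 2424 and 3162 in the Snf5-/- arrays, and 387, 389.9, 418 and 607 in the Brg1-/- arrays. The other Smarca4 probe set measured 1049 ± 99.5 in wild type and 217 ± 58.5 in Brg1-/-. In Snf5-/- the log2 change of Smarca4 was 0.37 ± 0.15 and did not pass (adjusted p = 0.110). In Brg1-/- the log2 change of Smarcb1 was 0.45 ± 0.10 (adjusted p = 0.00755) on the quantile-normalized scale and -0.08 (adjusted p = 0.728) on the deposited scale, so its direction depended on the scale. Smarca2, which encodes Brm, the alternative ATPase of the complex, measured 177 ± 65.2 in wild type, 147 ± 46.0 in Snf5-/- and 133 ± 19 in Brg1-/-, and passed in neither mutant (adjusted p = 0.988 and 0.896).

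**Figure D2:**
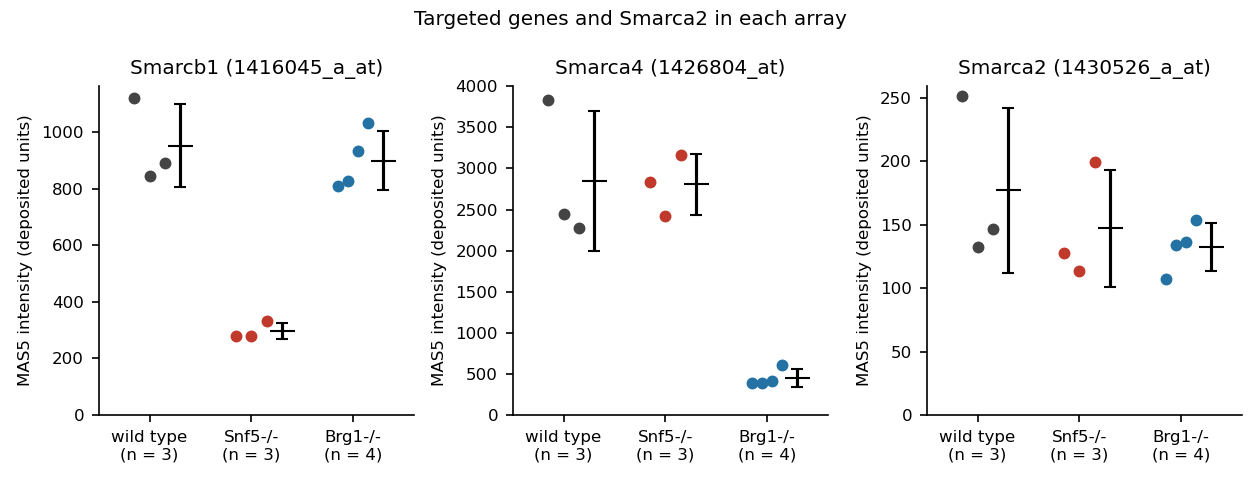
Deposited MAS5 intensity of Smarcb1, Smarca4 and Smarca2 in each array, with points for arrays and bars for the mean and SD of each group. The 3 Snf5-/- arrays lie between 279 and 331 for Smarcb1, and the 4 Brg1-/- arrays between 387 and 607 for Smarca4, below all wild type arrays.

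The comparison of Snf5-/- with wild type asks which transcripts change when the core subunit is lost. Of the 10 genes named as the largest rises, 6 were chemokine or interferon-induced genes. Ccl5 rose from 8.63 ± 1.67 (SD, n = 3) to 800.4 ± 793 intensity units (n = 3), which is at least 19.2-fold since the wild type arrays lay at background, and Cxcl10 rose by 6.04 ± 0.71 (SE, log2) and Cxcl11 by at least 11-fold. Snf5-/- replicate 2 lay far above replicates 1 and 3 for Ccl5 (1708 against 238 and 455) and Cxcl11 (1845 against 120 and 153). The folds of Ccl5 and Cxcl11 therefore rest partly on that array. Ifit1, Oasl2 and Ifi27l2a, all induced by interferon, rose by 4.66 ± 0.54, 4.58 ± 0.45 and at least 17.3-fold. The other largest rises were those of Mfap4, a microfibril-associated matrix protein (at least 8.79-fold), Wnt16, a secreted Wnt ligand (4.25 ± 0.77), Fndc1 (4.20 ± 0.53) and Agtr2, an angiotensin receptor (4.11 ± 0.46). Adjusted p for these 10 genes lay between 3.17e-05 and 0.00541. For Cxcl10, Oasl2, Wnt16 and Fndc1, 2 of the 3 wild type arrays lay at or below background, and for Agtr2 1 did, so the sizes of these rises rest partly on values below background.

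The largest falls in Snf5-/- came from several kinds of genes. Lists of epithelial and skeletal muscle markers did not pass (adjusted p = 0.170 and 0.503 on the deposited scale, 0.0783 and 0.371 after quantile normalization). Acta1, skeletal muscle actin, fell by 2.67 ± 0.32 (SE, log2), Prkg2, a cGMP-dependent kinase, by 2.67 ± 0.18, Msln, a mesothelial surface protein, by 2.78 ± 0.34, and Lce1h, a gene of the cornified envelope, by 2.56 ± 0.30, with adjusted p between 4.98e-06 and 0.000201. Serpinb2, a plasminogen activator inhibitor, fell at least 6.27-fold, Dsp, which encodes desmoplakin of desmosomes, fell by 3.24 ± 0.67, Rab27b by 3.21 ± 0.74, Akr1c18 by 3.07 ± 0.86 and Upk3b, a uroplakin, by 2.72 ± 0.81. For Dsp, Rab27b, Akr1c18 and Upk3b, 2 of the 3 Snf5-/- arrays lay at or below background, and for Msln 1 did, so the sizes of these falls are uncertain. F5, coagulation factor V, with all 3 Snf5-/- arrays at or below background, passed on the deposited scale (adjusted p = 0.0451) and not on the quantile-normalized scale (adjusted p = 0.0573). Some of these calls were lost on the deposited scale when a single array was left out. Without wild type replicate 1, adjusted p was 0.0620 for Serpinb2, 0.0521 for Dsp, 0.0504 for Rab27b, 0.0726 for Upk3b and 0.141 for F5, and without wild type replicate 2 it was 0.183 for Akr1c18. Serpinb2 was also lost without wild type replicate 2, and Akr1c18 and F5 were lost without any single wild type array, without Snf5-/- replicate 1 or 2 and, for F5, without Brg1-/- replicate 1. The rise of Mfap4 was lost without Snf5-/- replicate 2 (adjusted p = 0.196).

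Genes of the interferon response rose as a group in Snf5-/-. Of 32 measured members, 24 rose and 8 did not pass on the deposited scale, and 27 rose after quantile normalization, or 25 and 28 adjusted over the list alone, with a median log2 change of 2.05. Of the 10 measured genes of MHC class I and antigen processing, 6 rose on the deposited scale and 9 after quantile normalization, or 9 and 9 adjusted over the list alone, with a median of 1.18. Tap1, Psmb8 and Psmb9 were written into both lists, so in every comparison the results of these lists are not separate. Psmb10, an immunoproteasome subunit, rose by 1.40 ± 0.21, Tap1, a peptide transporter, by 1.34 ± 0.19, Tapbp, its partner tapasin, by 1.19 ± 0.18 and Erap1, a peptide-trimming protease, by 1.17 ± 0.20 (SE, log2). Erap1 was lost on the deposited scale without Snf5-/- replicate 3 (adjusted p = 0.0648). Camera gave adjusted p = 6.35e-40 on the deposited and 1.71e-17 on the quantile-normalized scale for the interferon list, and 1.26e-09 and 2.26e-06 for the MHC class I list. The interferon list had adjusted p = 0.315 with an estimated correlation on the deposited scale, and the MHC class I list had adjusted p = 0.463 with an estimated correlation. As a list, markers of macrophages and leukocytes moved with these genes in 1 array. Their mean was 1.67 (log2, relative to the mean of all arrays) in Snf5-/- replicate 2, against -0.21 and -0.39 in the other Snf5-/- arrays. Single markers differed on the deposited scale. C1qb, C1qc and Adgre1 lay above every wild type array in every Snf5-/- array. Lyz2, Cd53 and Laptm5 lay below every wild type array in Snf5-/- replicates 1 and 3. The mean log2 change of the 15 measured leukocyte markers in Snf5-/- was 0.66 ± 0.20 (SE over genes) with all arrays and 0.0067 ± 0.16 without replicate 2, on the quantile-normalized scale. Without that array, 22 interferon genes rose on the deposited and 25 on the quantile-normalized scale, with a median of 1.64 on the latter, and 4 and 8 genes of the MHC class I list rose.

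The list of G2/M and mitosis genes was also higher in Snf5-/-. Of 32 measured members, 8 rose on the deposited scale and 21 after quantile normalization, or 11 and 23 adjusted over the list alone, none fell, and the median log2 change was 0.76. Bub1b, a spindle checkpoint kinase, rose by 1.93 ± 0.30, Nusap1, a spindle protein, by 1.26 ± 0.21, Cdk1, the mitotic kinase, by 1.18 ± 0.19 and Ube2c, a ubiquitin-conjugating enzyme of mitotic exit, by 1.02 ± 0.13 (SE, log2). The calls of Cdk1 and Ube2c were lost on the deposited scale without Snf5-/- replicate 1 (adjusted p = 0.0680 and 0.0572). The camera test gave adjusted p = 4.82e-14 and 6.92e-10 on the deposited and quantile-normalized scales, with adjusted p = 0.546 with an estimated correlation on the former. Of the 32 measured genes of DNA replication and G1/S, 0 rose and 2 fell on the deposited scale and 2 rose and 1 fell after quantile normalization, with a camera adjusted p of 0.0880 and 0.0919 and a mean log2 change of 0.21 ± 0.06 (SE over genes) after quantile normalization. At an unadjusted p, the count of all tested genes past 0.05 was 2906 on the deposited scale.

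Smaller sets of genes changed in the p53 target, extracellular matrix, imprinted and histone lists in Snf5-/-. Of 29 p53 targets, 5 rose and 2 fell on the deposited scale and 14 rose and 1 fell after quantile normalization, or 6 and 3 against 15 and 1 adjusted over the list alone. Btg2, an antiproliferative gene, rose by 2.01 ± 0.19, Fas, a death receptor, by 1.55 ± 0.31 and Pltp, a phospholipid transfer protein, by 1.36 ± 0.16, while Perp, a desmosomal protein, fell by 2.03 ± 0.25 (SE, log2). Of 39 extracellular matrix genes, 11 rose and 7 fell on the deposited scale and 15 rose and 5 fell after quantile normalization, or 13 and 7 against 20 and 6 adjusted over the list alone. Col11a1, a fibrillar collagen, rose by 2.61 ± 0.16, Fbn2, a fibrillin, by 1.98 ± 0.17 and Fbln5, an elastic fibre protein, by 1.51 ± 0.10, and Efemp1 fell by 1.5 ± 0.14. Of 15 imprinted genes, 7 rose and 3 fell on the deposited scale and 7 rose and 2 fell after quantile normalization, or 7 and 3 against 8 and 2 adjusted over the list alone. Mest rose by 2.43 ± 0.22, Dlk1, a secreted Notch ligand relative, by 2.39 ± 0.40 and Meg3, a noncoding RNA, by 1.62 ± 0.18, and Peg3 fell by 0.92 ± 0.15. Of 8 histone genes, H2az2 alone rose on the deposited scale and 2 rose after quantile normalization, or 0 and 5 adjusted over the list alone. H2az2 rose by 0.89 ± 0.15 and lost its deposited call without any 1 of 9 arrays, all but Snf5-/- replicate 2, with a highest adjusted p of 0.159 without Snf5-/- replicate 1. Macroh2a2, H1f10 and Macroh2a1 did not pass, at 0.61 ± 0.24, 0.44 ± 0.21 and -0.07 ± 0.09.

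Camera gave the p53, extracellular matrix, imprinted and histone lists adjusted p of 0.000101, 2.07e-06, 0.00173 and 0.0441 on the deposited scale, and 3.41e-05, 0.000468, 0.0161 and 0.0207 after quantile normalization, all upwards. The histone call was the least stable. Not counting both other list tests, it passed in 15 of 24 alternatives, while the other 3 lists passed in all 24. The histone list was lost without wild type replicate 1 (adjusted p = 0.0744), wild type replicate 3 (0.0765) or Snf5-/- replicate 1 (0.197). On the deposited scale these lists had adjusted p = 0.723, 0.650, 0.723 and 0.723 with an estimated correlation. In all, 13 lists passed on the deposited scale, 10 upwards and 3 downwards, 9 after quantile normalization and 7 on both, and the gene lists in Snf5-/- against wild type past the threshold numbered 8 without wild type replicate 1. Lists that passed only on the deposited scale were adhesion and cytoskeleton genes (lower, adjusted p = 0.00975), glycolysis and hypoxia response (lower, 0.0344), MYC targets and ribosome biogenesis (lower, 0.0441), Hedgehog pathway (higher, 0.0259), macrophage and leukocyte markers (higher, 0.00390) and chondrocyte and osteoblast markers (higher, 0.0335). Each of these 6 was also lost on the deposited scale without a single array, at adjusted p of 0.0837 for adhesion, 0.246 for glycolysis and 0.195 for MYC targets without Snf5-/- replicate 3. It was 0.0862 for Hedgehog and 0.201 for chondrocyte markers without wild type replicate 1, and 0.927 for leukocyte markers without Snf5-/- replicate 2. Other arrays did the same for Hedgehog (0.0516 without Snf5-/- replicate 3), glycolysis (0.0878 without wild type replicate 2), MYC targets (0.0976 without wild type replicate 1, 0.0568 and 0.0510 without Brg1-/- replicates 1 and 2), leukocyte (0.169 without wild type replicate 1) and chondrocyte markers (0.0757 without Snf5-/- replicate 2). Oxidative phosphorylation (higher, 0.0197) and the DNA and histone methylation machinery (higher, 0.0385) passed only after quantile normalization. The former pointed lower on the deposited scale (adjusted p = 0.745). With an estimated correlation, 0 lists passed on either scale, against 6 with fry on the deposited scale and 13 with fry after quantile normalization.

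Across all genes, 1618 changed in Snf5-/- on the deposited scale, 265 higher and 1353 lower. After quantile normalization 1519 genes passed, 892 higher and 627 lower, and 265 higher and 626 lower genes passed on both scales. Wild type and Snf5-/- arrays did not overlap for 34.7% of genes on the deposited scale, where chance gives 10%. The number of genes changed in Snf5-/- against wild type was 935 without wild type replicate 1 and 920 without Snf5-/- replicate 1.

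The comparison of Brg1-/- with wild type asks the same question for the ATPase subunit. Both cell cycle lists were higher by camera at its preset correlation. Of 32 measured G2/M and mitosis genes, 26 rose on the deposited scale and 32 after quantile normalization, or 30 and 32 adjusted over the list alone, with a median log2 change of 1.44. Bub1b rose by 2.88 ± 0.28, Ccnb2, a mitotic cyclin, by 2.16 ± 0.18, Cdc20, an activator of the anaphase-promoting complex, by 2.04 ± 0.18 and Ube2c by 1.96 ± 0.12 (SE, log2), with adjusted p between 1.93e-06 and 2.67e-05 (3 wild type and 4 Brg1-/- arrays). Of 32 measured genes of DNA replication and G1/S, 11 rose and 1 fell on the deposited scale and 25 rose after quantile normalization, or 8 and 26 rose adjusted over the list alone, with a median of 0.78. Mcm5, a subunit of the replicative helicase, rose by 1.48 ± 0.17, Uhrf1, a partner of the maintenance DNA methyltransferase, by 1.45 ± 0.20, Rfc4, a clamp loader subunit, by 1.37 ± 0.22 and Prim1, a primase subunit, by 1.19 ± 0.19. Prim1 lost its deposited call without wild type replicate 3 (adjusted p = 0.0585). Camera gave adjusted p = 1.07e-43 and 9.57e-22 for G2/M and 1.92e-14 and 1.46e-10 for G1/S on the deposited and quantile-normalized scales. The G2/M list had adjusted p = 0.197 with an estimated correlation on the deposited scale, and the G1/S list had adjusted p = 0.442 with an estimated correlation.

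The largest rises in Brg1-/- were those of Ccl5, at least 7.70-fold above background, Fndc4, a fibronectin type III domain protein (4.22 ± 0.45, SE, log2), Wnt16 (4.16 ± 0.72), Gas1, a co-receptor of Hedgehog ligands (3.92 ± 0.31), Fndc1 (3.73 ± 0.50), Kcnk1, a potassium channel (3.65 ± 0.96), Cdo1, a cysteine dioxygenase (3.43 ± 0.20), Cxcl10 (3.4 ± 0.66), Kifc1, a spindle kinesin (3.38 ± 0.62), and Cxcl11, at least 2.70-fold. Adjusted p of these genes lay between 1.35e-06 and 0.0136. The largest falls were those of Qpct, a glutaminyl cyclase, at least 3.98-fold, Serpinb2, at least 5.89-fold, Mmp13, a collagenase (fell by 4.08 ± 0.74), Acta1 (fell by 3.79 ± 0.30), Akr1c18, at least 3.88-fold, Fabp7, a fatty acid binding protein of glia, at least 2.62-fold, Dsp, at least 5.25-fold, Lce1f, at least 2.93-fold, Tac1, the precursor of substance P (fell by 3.31 ± 0.64), and Tfpi2, a protease inhibitor (fell by 3.22 ± 0.49). Adjusted p of these genes lay between 5.58e-06 and 0.0131. The sizes of some changes rest on arrays at or below background, which were 2 of 3 wild type arrays for Wnt16, Fndc1, Kcnk1 and Cxcl10, 1 for Fndc4, and 2, 3 and 1 of 4 Brg1-/- arrays for Mmp13, Tac1 and Tfpi2. The call of Qpct was lost on the deposited scale without wild type replicate 1 (adjusted p = 0.0641) and without wild type replicate 2.

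The interferon response list was higher in Brg1-/- too. Of 32 members, 12 rose and 2 fell on the deposited scale and 22 rose after quantile normalization, or 12 and 2 against 24 and 0 adjusted over the list alone, with a median log2 change of 1.01. Oasl2, with 2 of 3 wild type arrays at or below background, rose by 2.87 ± 0.42 and Igtp, an immunity-related GTPase, by 1.74 ± 0.28 (SE, log2). Of 10 genes of MHC class I and antigen processing, 0 rose and 2 fell on the deposited scale, H2-K1 and B2m, and 5 rose after quantile normalization, or 0 and 2 against 6 and 0 adjusted over the list alone. Tap2, a peptide transporter, had a change of 0.87 ± 0.17 and Psmb9, an immunoproteasome subunit with 1 wild type array at or below background, of 1.44 ± 0.49, and both passed only after quantile normalization. The values of H2-K1, a class I heavy chain, and of B2m, the class I light chain, were -0.26 ± 0.24 and 0.02 ± 0.13 after quantile normalization and did not pass there. B2m lost its deposited call without wild type replicate 2 (adjusted p = 0.0569). Camera gave adjusted p = 9.79e-20 and 2.82e-07 for the interferon list and 0.0103 and 0.0216 for MHC class I, on the deposited and quantile-normalized scales, and MHC class I did not pass with a 60th percentile filter (adjusted p = 0.0877). These had adjusted p = 0.442 and 0.666 on the deposited scale with an estimated correlation. The 15 leukocyte markers had a mean log2 change of 0.27 in Brg1-/- after quantile normalization, with 2 higher and 0 lower.

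**Figure D3:**
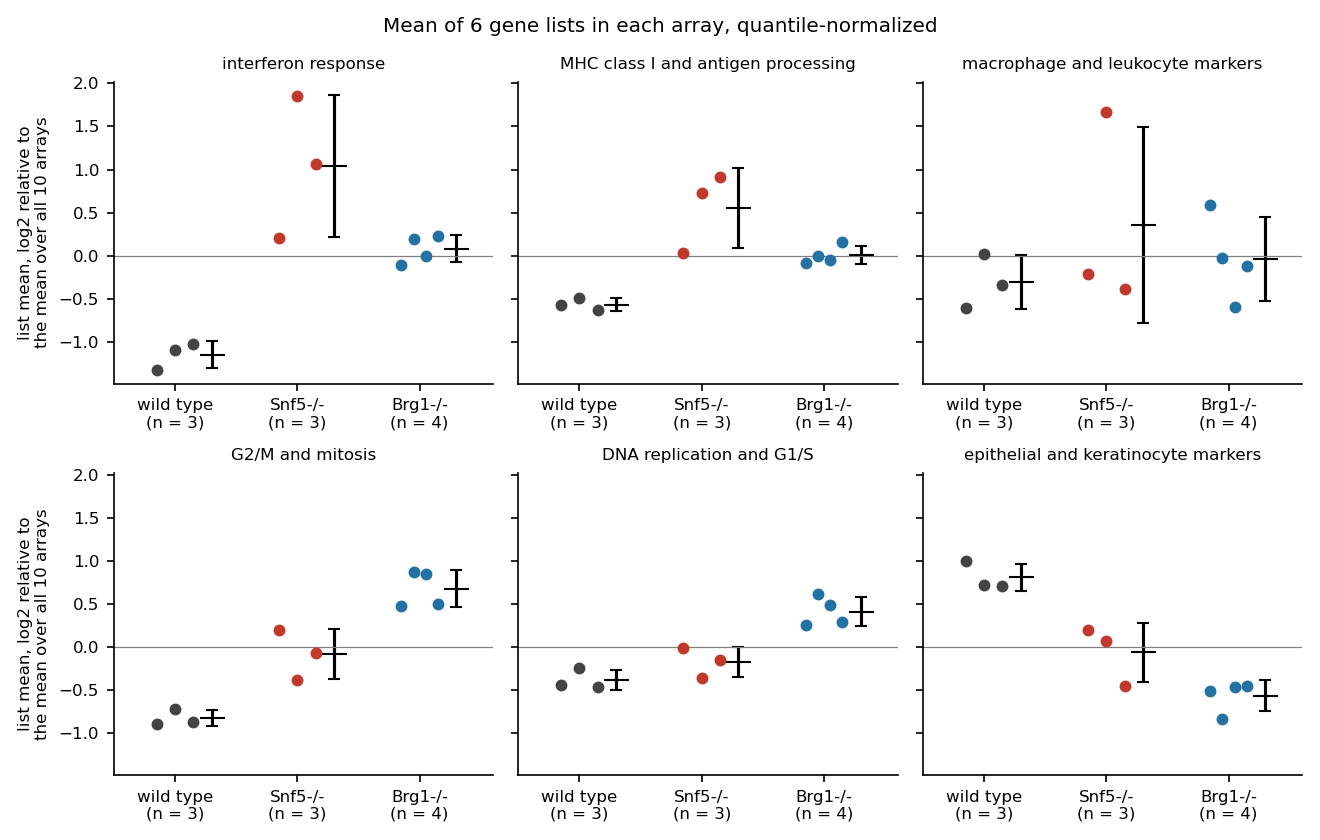
Mean of 6 gene lists in each array, as log2 relative to the mean over all 10 arrays, after quantile normalization, with points for arrays and bars for the mean and SD of each group. Interferon genes average -1.15 in wild type, 1.04 in Snf5-/- and 0.08 in Brg1-/-, G2/M genes average -0.82, -0.08 and 0.68, and the leukocyte markers of Snf5-/- replicate 2 lie at 1.67.

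The lists of contractile, adhesion and glycolysis genes were lower in Brg1-/- by camera at its preset correlation, and not with an estimated correlation. Most of their members did not fall after quantile normalization. Of 24 smooth muscle and contractile genes, 18 fell on the deposited scale and 10 fell and 3 rose after quantile normalization, with the same counts adjusted over the list alone. Lmod1, an actin nucleator, fell by 1.68 ± 0.29, Mylk, myosin light chain kinase, by 1.56 ± 0.28, Ccn2, connective tissue growth factor, by 1.46 ± 0.17 and Csrp1 by 0.52 ± 0.15 (SE, log2). Of 24 adhesion and cytoskeleton genes, 20 fell and 1 rose on the deposited scale and 9 fell and 2 rose after quantile normalization, or 20 and 1 against 10 and 3 adjusted over the list alone. The integrin genes Itga3, Itga6, Itga5 and Itgb1 fell by 1.72 ± 0.20, 1.37 ± 0.11, 1.36 ± 0.20 and 0.46 ± 0.11. Of 21 glycolysis and hypoxia genes, 16 fell on the deposited scale and 8 after quantile normalization, or 17 and 8 adjusted over the list alone. The glycolytic enzyme genes Pgam1, Pfkp, Aldoa and Pfkl fell by 0.75 ± 0.08, 0.73 ± 0.15, 0.52 ± 0.10 and 0.48 ± 0.14. Of 8 histone genes, 2 rose and 1 fell on the deposited scale and 5 rose after quantile normalization, or 2 and 1 against 5 and 0 adjusted over the list alone. The variant histone genes H2az2 and H2az1 rose by 1.39 ± 0.14 and 1.20 ± 0.15, and H2az1 lost its deposited call without wild type replicate 2 or 3 or Brg1-/- replicate 2 or 3, with a highest adjusted p of 0.129 without wild type replicate 3. Macroh2a1 fell on the deposited scale and had a value of 0.05 ± 0.09 after quantile normalization. H1f2, a linker histone, passed only after quantile normalization, at 0.28 ± 0.09, and had a value of -0.37 on the deposited scale.

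Camera gave the contractile, adhesion, glycolysis and histone lists adjusted p of 0.000934, 0.00145, 0.00340 and 0.00340 on the deposited scale, and 0.00959, 0.0152, 0.0113 and 0.00205 after quantile normalization, the first 3 downwards and the histones upwards. On the deposited scale these lists had adjusted p = 0.666, 0.666, 0.558 and 0.535 with an estimated correlation. In all, 8 lists passed on the deposited scale, 5 upwards and 3 downwards, and the same 8 were among the 13 that passed after quantile normalization. Without Brg1-/- replicate 3, 13 gene lists in Brg1-/- against wild type passed on the deposited scale. Epithelial and keratinocyte markers (lower, adjusted p = 0.00865), CDK inhibitors and senescence genes (lower, 0.0363), oxidative phosphorylation (higher, 0.00428), the DNA and histone methylation machinery (higher, 0.00966) and p53 targets (higher, 0.0464) passed only after quantile normalization. On the deposited scale the direction of the oxidative phosphorylation list was lower, with adjusted p = 0.222. With an estimated correlation, 0 lists passed on either scale, against 14 with fry on the deposited scale and 19 with fry after quantile normalization.

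Across all genes, 3990 changed in Brg1-/- on the deposited scale, 288 higher and 3702 lower. After quantile normalization 2330 genes passed, 1250 higher and 1080 lower, and 288 higher and 1080 lower genes passed on both scales. Wild type and Brg1-/- arrays did not overlap for 53.1% of genes on the deposited scale and 39.4% after quantile normalization, where chance gives 5.71%.

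The next comparison asks how far the responses to loss of either subunit run together. Ccl5, Wnt16, Fndc1, Gas1 and Kcnk1 had the largest shared rises and Serpinb2, Dsp, Akr1c18, Acta1 and F5 the largest shared falls, ranked among genes past the threshold on the deposited scale. F5 did not pass in Snf5-/- after quantile normalization (adjusted p = 0.0573). All 3 Snf5-/- arrays and 3 of 4 Brg1-/- arrays lay at or below background for it. In Snf5-/- Gas1 rose from 412 ± 133 (SD, n = 3) to 5524 ± 3150.6 (n = 3) and Kcnk1 from 21.6 ± 30.2, with 2 of 3 wild type arrays at or below background, to 116 ± 48.6 intensity units. The Snf5-/- call of Kcnk1 was lost without Snf5-/- replicate 2 (adjusted p = 0.0606). The Snf5-/- calls of Serpinb2, Dsp, Akr1c18 and F5 were lost without single arrays at adjusted p of up to 0.0620 (without wild type replicate 1), 0.0521 (without wild type replicate 1), 0.183 (without wild type replicate 2) and 0.141 (without wild type replicate 1), and the Brg1-/- call of F5 at 0.0544 (without wild type replicate 3, and lost without wild type replicate 1 too). Serpinb2 was also lost without wild type replicate 2, and Akr1c18 and F5 without the other wild type arrays and Snf5-/- replicate 1 or 2, F5 also without Brg1-/- replicate 1. On the deposited scale 156 genes were higher and 1242 lower in both mutants, and after quantile normalization 628 were higher and 467 lower. Independent lists of these sizes would share 9.09 higher and 596 lower genes on the deposited scale and 133 and 80.6 after quantile normalization. Simulated unchanged groups sharing the wild type arrays gave a mean of 0 shared calls in 100 runs, against 109 genes (110.0 after quantile normalization) in the same direction at an unadjusted p in those runs and 2430 (1889 after quantile normalization) in the data. In these runs genes varied independently, so few or no shared calls were bound to follow. Deviations that many genes of the wild type arrays have in common are left out of them. Shared genes made up 86.4% of Snf5-/- calls and 35% of Brg1-/- calls on the deposited scale, and 72.1% and 47.0% after quantile normalization. The count of 1398 shared genes was 768 without wild type replicate 1 and 809 without Snf5-/- replicate 1.

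Across genes, the log2 changes of both mutants had Pearson r = 0.78 on the deposited scale and 0.77 after quantile normalization, where genes are not independent replicates, and simulated unchanged groups gave a mean r of 0.53 from the shared wild type arrays alone. The covariance was 0.278 on the deposited and 0.269 on the quantile-normalized scale, against 0.0439 and 0.0360 in the simulations. Since the simulations leave out deviations common to many genes of an array, they are not a full benchmark for r or the covariance. Only 5 genes passed in opposite directions on the deposited scale, and 5 after quantile normalization. Those named here are the ones of the deposited scale. Lsp1, an actin-binding protein of leukocytes, rose by 1.42 ± 0.21 in Snf5-/- and fell by 0.80 ± 0.19 in Brg1-/- (SE, log2), and passed on both scales. Ifitm1, H2-K1, Sdc4 and Igf2r were higher in Snf5-/- (1.31 ± 0.31, 1.08 ± 0.26, 1.05 ± 0.21 and 0.96 ± 0.18), but in Brg1-/- they passed on the deposited scale only, with values of -0.75 ± 0.29, -0.26 ± 0.24, -0.21 ± 0.19 and 0.01 ± 0.17 after quantile normalization. The deposited Snf5-/- calls of these 4 genes were lost without single arrays, with the highest adjusted p at 0.129 for Ifitm1 and 0.166 for H2-K1 without Snf5-/- replicate 3, 0.0602 for Sdc4 without wild type replicate 1 and 0.228 for Igf2r without Snf5-/- replicate 2. Ifitm1 and H2-K1 were also lost without any single wild type array or Snf5-/- replicate 2, H2-K1 without Brg1-/- replicate 2 or 3, and Igf2r without any other array except wild type replicate 1 and Snf5-/- replicate 3. In Brg1-/- the call of Sdc4 was lost without wild type replicate 2 (adjusted p = 0.0582) and that of Igf2r without wild type replicate 1 (0.116) and without Brg1-/- replicate 1 or 2.

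**Figure D4:**
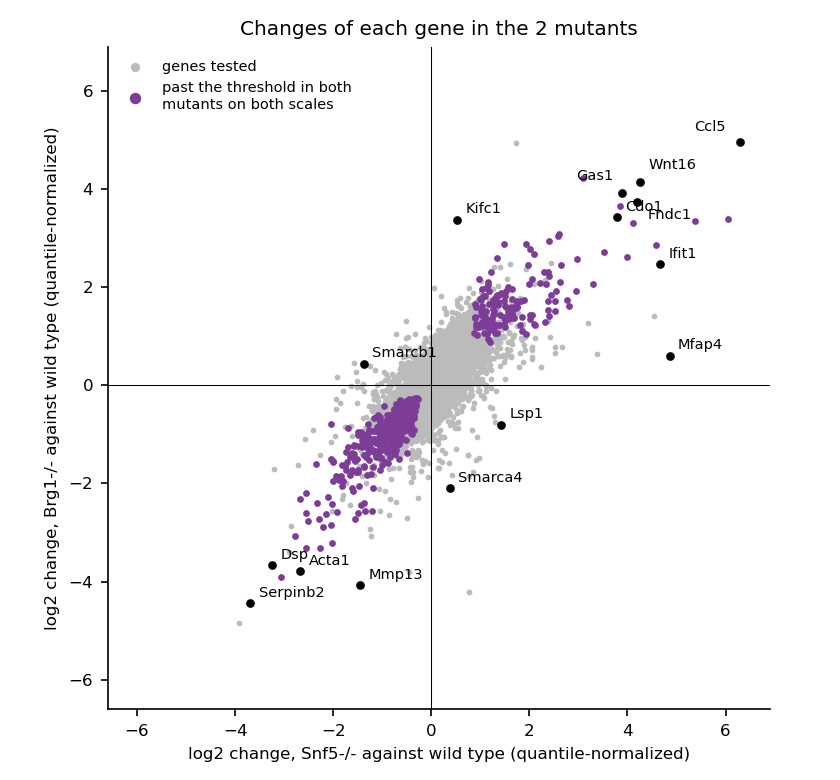
Log2 change of each tested gene in Snf5-/- (x axis) and Brg1-/- (y axis) against wild type after quantile normalization, with genes past the threshold in both mutants on both scales in purple. Smarcb1 lies at -1.37 on the x axis, Smarca4 at -2.10 on the y axis, and Ccl5, Wnt16, Fndc1 and Gas1 rise in both.

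The direct comparison of Brg1-/- with Snf5-/- tests which genes respond differently to loss of either subunit. As lists, cell cycle genes were higher in Brg1-/-, and interferon, MHC class I, matrix and imprinted genes were higher in Snf5-/-. This held by camera at its preset correlation. Of 32 G2/M genes, 6 were higher in Brg1-/- on the deposited scale and 17 after quantile normalization, or 22 and 26 adjusted over the list alone, and of 32 G1/S genes the counts were 2 and 15, or 6 and 22 adjusted over the list alone. Differences were 1.20 ± 0.18 (SE, log2) for Ccnb2, 1.07 ± 0.13 for Ccna2, 0.98 ± 0.17 for Birc5, 0.94 ± 0.12 for Ube2c, 1.09 ± 0.20 for Lig1 and 0.98 ± 0.17 for Mcm5. Each of these calls was lost on the deposited scale when any of several single arrays was left out. Adjusted p was up to 0.0714 for Ccnb2 without Snf5-/- replicate 2, 0.0992 for Lig1 without Snf5-/- replicate 1, and 0.0639 for Ccna2, 0.138 for Birc5, 0.126 for Ube2c and 0.0786 for Mcm5 without Brg1-/- replicate 2. All 6 were lost without Brg1-/- replicate 2 or 3, Ccna2 and Lig1 also without Snf5-/- replicate 1, Ccnb2 without Snf5-/- replicate 2, Mcm5 without Snf5-/- replicate 2 or 3, and Birc5 and Ube2c without wild type replicate 2, any Snf5-/- array or Brg1-/- replicate 1. Camera gave adjusted p = 6.09e-31 and 3.85e-21 for G2/M and 8.25e-20 and 7.97e-16 for G1/S on the deposited and quantile-normalized scales, and both lists had adjusted p = 0.453 with an estimated correlation on the deposited scale and 0.216 on the quantile-normalized scale.

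Of 32 interferon genes, 13 were lower in Brg1-/- than in Snf5-/- on the deposited scale and 6 after quantile normalization, or 23 and 16 adjusted over the list alone, and of 10 MHC class I genes 4 and 2, or 7 and 5 adjusted over the list alone. Bst2, an antiviral membrane protein, differed by -1.85 ± 0.23 (SE, log2), Ifit1 by -2.18 ± 0.50, Ifih1, a sensor of double-stranded RNA, by -1.13 ± 0.28, H2-K1 by -1.34 ± 0.24 and Psmb10 by -1.0 ± 0.20. Snf5-/- replicate 1 did not stand apart from Brg1-/-. Its list mean was 0.20 (log2) for interferon and 0.03 for MHC class I genes, within the Brg1-/- ranges of -0.10 to 0.23 and -0.08 to 0.16, and with array weights the MHC class I list did not pass (adjusted p = 0.113). The leukocyte markers had a mean difference of -0.39 between the mutants, with 1 lower on the deposited scale, 0 passing after quantile normalization and Snf5-/- replicate 2 standing apart as given above. Of 39 extracellular matrix genes, 13 were lower in Brg1-/- on the deposited scale and 7 after quantile normalization, or 24 and 11 adjusted over the list alone, with Eln, elastin, at -1.38 ± 0.21 and the collagen genes Col1a2 and Col1a1 at -0.53 ± 0.08 and -0.57 ± 0.12. Of 15 imprinted genes, 5 and 5 were lower, or 8 and 7 adjusted over the list alone, with the cyclin-dependent kinase inhibitor Cdkn1c at -1.52 ± 0.20, Igf2r at -0.95 ± 0.17, the growth factor Igf2 at -0.48 ± 0.07 and Nnat at -1.41 ± 0.30. Camera gave adjusted p = 1.03e-11 for interferon, 0.000119 for MHC class I, 4.66e-08 for extracellular matrix and 3.20e-05 for imprinted genes on the deposited scale, and 5.54e-10, 0.000397, 1.93e-05 and 0.000597 after quantile normalization. On the deposited scale these lists had adjusted p = 0.568, 0.607, 0.557 and 0.557 with an estimated correlation.

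Lists of CDK inhibitor and senescence genes, p53 targets, and contractile, stress and inflammatory genes were lower in Brg1-/- than in Snf5-/- by camera at its preset correlation. Most of their members did not pass. Of 20 CDK inhibitor and senescence genes, 6 were lower on the deposited scale and 3 after quantile normalization, or 11 and 6 adjusted over the list alone, and of 29 p53 targets 4 and 3, or 11 and 6 adjusted over the list alone. Cdkn1a, which encodes the inhibitor p21 and belongs to both lists, differed by -0.86 ± 0.10 (SE, log2), Igfbp5 by -1.26 ± 0.29 and Plk3, a stress-responsive kinase, by -2.61 ± 0.48. The size for Plk3 is uncertain, since Brg1-/- replicate 4 lay below background (14.1 against 43) and replicate 3 close to it (43.7 against 42.5). The mean of the CDK inhibitor list was 0.84 (log2) in Snf5-/- replicate 2 and -0.20 and 0.09 in the other Snf5-/- arrays. Replicate 1 lay within the Brg1-/- range of -0.55 to -0.08. The CDK inhibitor and senescence list also holds cytokine genes. Il6, Cxcl1, Ccl2 and Ccl7 were written into it and into the inflammatory list below, so the results of these lists are not separate. Of 24 contractile genes, 5 were lower on the deposited scale and 2 lower and 1 higher after quantile normalization, or 14 lower against 4 lower and 1 higher adjusted over the list alone, with Actg2, smooth muscle actin, at -1.97 ± 0.22 and Myh11, smooth muscle myosin, at -1.82 ± 0.25. Snf5-/- replicate 3, with a contractile list mean of -0.16, lay within the Brg1-/- range of -0.38 to 0.10. Of 24 genes of ATF4 and the unfolded protein response, 4 and 3 were lower, or 12 and 5 adjusted over the list alone, with Herpud1 at -0.90 ± 0.19, Ddit3 at -0.64 ± 0.14 and Xbp1, a transcription factor of that response, at -0.59 ± 0.10. Herpud1 and Ddit3 lost their deposited calls without Brg1-/- replicate 2 (adjusted p = 0.0537 and 0.0972), and Ddit3 also without Snf5-/- replicate 3. Of 22 inflammatory and NF-kB target genes, 3 and 1 were lower, or 11 and 1 adjusted over the list alone, with the adhesion receptor Vcam1 at -1.05 ± 0.24. The call of this list rested on Snf5-/- replicate 2, the array that stood apart for leukocyte markers. Its mean for the list was 1.37 (log2), against -0.44 and -0.10 in the other Snf5-/- arrays, and without it the direction turned and the list did not pass (adjusted p = 0.928), nor did it with array weights (adjusted p = 0.426 for inflammatory cytokines and NF-kB targets). Camera gave these 5 lists, in this order, adjusted p of 0.000119, 0.00262, 9.01e-05, 0.000119 and 0.000233 on the deposited scale and 0.00201, 0.0141, 0.00706, 0.000816 and 0.00133 after quantile normalization. They had, on the deposited scale, adjusted p = 0.541, 0.607, 0.607, 0.607 and 0.607 with an estimated correlation.

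MYC target and cholesterol synthesis genes were higher in Brg1-/- than in Snf5-/- as lists by camera at its preset correlation. Single arrays overlapped. For MYC targets Brg1-/- replicate 4 had a list mean of -0.13 (log2), within the Snf5-/- range of -0.22 to -0.05. For cholesterol synthesis Snf5-/- replicate 2 had 0.19, within the Brg1-/- range of -0.11 to 0.35. Of 27 MYC targets, 0 passed on the deposited scale and 2 were higher after quantile normalization, or 0 and 7 adjusted over the list alone, with Ncl, nucleolin, at 0.50 ± 0.11 (SE, log2) and Wdr12 at 0.54 ± 0.14. Of 17 cholesterol synthesis genes, 0 passed on the deposited scale and 1 was higher after quantile normalization, or 1 lower against 6 higher and 1 lower adjusted over the list alone, with Lss, lanosterol synthase, at 0.78 ± 0.18. The value of Lss depended on its probe set, and without probe sets that may detect several transcripts it was -0.0092 on the deposited scale, against 0.61 with them (Lss: genes different between Brg1-/- and Snf5-/-). From camera, adjusted p was 0.00304 and 1.25e-05 for MYC targets and 0.000119 and 0.00141 for cholesterol synthesis, with adjusted p = 0.628 and 0.607 with an estimated correlation on the deposited scale. In all, 16 lists passed on the deposited scale, 5 higher and 11 lower in Brg1-/-, 14 after quantile normalization and 13 on both. TGF-beta targets (lower, adjusted p = 0.0423), Hox genes (higher, 0.0217) and glycolysis (lower, 0.04998) passed only on the deposited scale, and histones (higher, 0.0208) only after quantile normalization. On the deposited scale TGF-beta targets were lost without wild type replicate 1 (adjusted p = 0.0670) or Brg1-/- replicate 2 (0.118) or 3 (0.0984). Hox genes were lost without Snf5-/- replicate 2 (0.0552) or Brg1-/- replicate 2 (0.0537). Glycolysis was lost without any 1 of 7 arrays, all but Snf5-/- replicate 3 and Brg1-/- replicates 2 and 3, with the highest adjusted p at 0.617 without Snf5-/- replicate 2. With an estimated correlation 0 lists passed on either scale, and with fry 0 passed on the deposited scale and 4 after quantile normalization. At an unadjusted p, 1798 genes passed 0.05 on the deposited scale. The lists of SWI/SNF subunits, immediate early genes, cytosolic ribosomal proteins, NRF2 and glutathione genes, adipocyte, endothelial, neural and glial, and skeletal muscle markers passed in none of the 3 comparisons on either scale, with a smallest adjusted p of 0.0660.

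Among single genes, the largest differences upwards in Brg1-/- were those of Kifc1 (2.86 ± 0.62, SE, log2), Smarcb1 (1.82 ± 0.10), St8sia3, a sialyltransferase (1.77 ± 0.46), and Il13ra1, a cytokine receptor (1.49 ± 0.36). Erdr1 passed on the deposited scale and not after quantile normalization (1.92 ± 0.55, adjusted p = 0.0714). The largest downwards were those of Mfap4 (at least 5.58-fold lower), Fabp7 (at least 1.93-fold lower), Ifi27l2a (-3.14 ± 0.46) and C1s1, a complement protease (-2.73 ± 0.49). Ifi202b, an interferon-inducible gene, passed on the deposited scale and not after quantile normalization (-4.99 ± 1.34, adjusted p = 0.0573), with 3 of 4 Brg1-/- arrays at or below background. For Kifc1, St8sia3 and Il13ra1 this held for 1 of 3 Snf5-/- arrays. Single arrays ended some of these calls on the deposited scale, with the highest adjusted p at 0.127 for St8sia3 and 0.0947 for Erdr1 without Brg1-/- replicate 2, 0.142 for Il13ra1 and 0.181 for Fabp7 without Snf5-/- replicate 1, and 0.243 for Mfap4 without Snf5-/- replicate 2. St8sia3 was lost without any Brg1-/- array or Snf5-/- replicate 3, Erdr1 without wild type replicate 1 or Brg1-/- replicate 1, 2 or 3, Il13ra1 also without Brg1-/- replicate 2, 3 or 4, Fabp7 also without wild type replicate 2 or 3 or Snf5-/- replicate 2, and Mfap4 without any Snf5-/- array. Across all genes, 361 differed on the deposited scale, 31 higher and 330 lower in Brg1-/-, and 373 after quantile normalization, 180 higher and 193 lower, with 30 higher and 176 lower on both. Brg1-/- and Snf5-/- arrays did not overlap for 22.4% of genes on the deposited scale, where chance gives 5.71%. The deposited number of genes different between Brg1-/- and Snf5-/- was 756 without wild type replicate 1, 239 without Snf5-/- replicate 1, and 212, 128 and 176 without Brg1-/- replicates 1, 2 and 3.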

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

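The tests of brightness, interferon genes and G2/M genes below were chosen only after the results were seen, while the other splits of the arrays, the genes near the targeted genes and the neighbouring genes were chosen before.

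In Brg1-/- against wild type most called genes were lower on the deposited scale. Arrays of different overall brightness left unscaled cannot be told apart from a general fall of transcripts. After quantile normalization 46.4% of called genes were lower, but that scale brings the median change near 0 whatever the cause, so this share decides nothing. A lower gain in hybridization, staining or scanning would lower the spiked controls as well, and these differed by -0.031 (log2), far less than the -0.41 of the array medians. RNA degradation in the Brg1-/- arrays would raise the beta-actin ratio of 3-prime to 5-prime signal, which differed by -0.035. The Gapdh ratio went the other way, by 0.09 ± 0.04 (exact permutation p = 0.0571), and both lay under the bound of 0.5 by more than 2 SE. A lower amount of labelled RNA also stays open and was not tested.

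The interferon response list was higher in both mutants than in wild type by camera at its preset correlation, and not with an estimated correlation (adjusted p = 0.315 and 0.442 on the deposited scale). Of 32 genes, 24 were higher in Snf5-/- and 12 higher and 2 lower in Brg1-/- on the deposited scale, and 27 and 22 were higher after quantile normalization. Array brightness would lower them in the dimmer mutants, whereas the smaller of the 2 median log2 changes on the deposited scale was 0.58. Leukocytes among the mutant cells would bring their own markers, and these had a mean log2 change of 0.66 ± 0.20 (SE over genes) in Snf5-/-, against 2.18 ± 0.27 for the interferon genes, and 0.0067 without Snf5-/- replicate 2. Between the Snf5-/- arrays the list means had an SD of 1.14 for the leukocyte markers and 0.82 for the interferon genes (n = 3). The SE over genes leaves this spread out. On the deposited scale the markers C1qb and C1qc lay above every wild type array in every mutant array, while Lyz2, Cd53 and Laptm5 did not. Leukocytes among the mutant cells therefore stay open. Embryos or strain background differing between the cultures could raise the genes too. The SD of the list mean over the wild type arrays was 0.16, and the labels do not give the embryo of each array, so this cannot be told apart from an effect of genotype. The Y-linked genes Eif2s3y, Uty and Kdm5d were higher in every wild type array than in any mutant array on the deposited scale. The wild type arrays were the brightest on that scale. A difference in sex between the cultures stays open too. Retroviral delivery of Cre, and whether the wild type cells received the same virus, stay open and were not tested.

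The G2/M list was higher in both mutants than in wild type by camera at its preset correlation, and not with an estimated correlation (adjusted p = 0.546 and 0.197 on the deposited scale). Of 32 genes, 8 were higher in Snf5-/- and 26 in Brg1-/- on the deposited scale, and 21 and 32 after quantile normalization. Array brightness would lower them on the deposited scale, where the smaller of the 2 median log2 changes was 0.52. A larger share of cycling cells in Brg1-/- may account for part of it, since 78.1% of the DNA replication and G1/S genes were higher there after quantile normalization. In Snf5-/- 6.25% of those genes were higher on that scale. The simulations found 12% of changes at a log2 change of 0.5, but with the spread of the deposited scale. Recovery after quantile normalization was not simulated, so how many changes this share could miss is not known. No conclusion is drawn from it. The mean log2 change in Snf5-/- was 0.21 ± 0.06 (SE over genes) for the DNA replication and G1/S list. For G2/M it was 0.75 ± 0.07. Between the Snf5-/- arrays the means of these lists had an SD of 0.17 and 0.29 (n = 3), which the SE over genes leaves out. A larger share of cycling cells cannot be told apart from other accounts. Loss of the subunits acting on mitotic genes directly was not tested.

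Of the 10 splits of wild type and Snf5-/- arrays into groups of 3, 1 gave as many genes, the real one with 1618, and the highest other gave 0, which is too few splits for a share under 0.05. For Brg1-/- against wild type 1 of 35 splits gave as many, the real one with 3990, against 812 at most in another. For Brg1-/- against Snf5-/- it was 1 of 35 as well, with 361 against 111. The share of 0.0286 lay under 0.05 in both, but it is the smallest that 35 splits allow. Other splits mix genotypes within a group, which widens the spread there, so the real split is favoured from the start. The labels also do not show that the arrays are independent, so chance was not excluded. Among the 50 measured genes on each side of Smarcb1, 21% passed in Snf5-/- on the quantile-normalized scale against 18.1% of other genes (one-sided Fisher exact p = 0.260), and around Smarca4 25.5% passed in Brg1-/- on that scale against 27.8% (exact p = 0.724). On the same scale, neighbouring genes passed in the same direction in 172 pairs in Snf5-/-, against 137 on average when shuffled (one-sided permutation p = 6e-04). Pairs whose symbols share their first 3 letters were left out, which only stands in for membership of a gene family. In Brg1-/- the count of 344 against 315 (one-sided permutation p = 0.03) lay within the middle 95% of the shuffles, which reached 346, so it is left open there.

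A total of 4 values stood apart from the other 3 Brg1-/- arrays by Dixon's test, for which chance gives about 1 in 20 and 5.55 were expected in 111 tests. Fas measured 343 in replicate 4 against 154 to 172, Itga6 647 in replicate 3 against 507 to 524, Smarca4 607 in replicate 4 against 387 to 418, and Xbp1 1479 in replicate 4 against 1279 to 1310. Among 1136 probe sets without a single gene name, which the comparisons of genes did not use, 35 were higher in Snf5-/- and 37 in Brg1-/- on both scales, and 97 and 137 were lower.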

How the results depend on the processing

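Cyclic loess and scaling to the hybridization controls were chosen only after the results were seen, and the other alternatives before the data were examined. The cause of a difference was not tested unless stated.

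On scales that remove array brightness, counts for Brg1-/- against wild type fell from 3990 to 2330 (quantile normalization), 2216 (arrays centred on their median) and 2426 (cyclic loess). Gene lists in Brg1-/- against wild type rose from 8 to 13 with quantile normalization, 13 with cyclic loess and 13 with a replicate block, and gene lists in Snf5-/- against wild type fell from 13 to 8 with centring. Scaling to hybridization controls gave 984 genes in Snf5-/- and 816 in both mutants. Without a filter, 172 genes differed between Brg1-/- and Snf5-/- and the correlation across genes was 0.67. No intensity trend gave 96 genes for that comparison. Array weights gave 4109 genes in Snf5-/-, 1572 between the mutants and 3411 in both mutants. At an adjusted p under 0.01, 671, 2483 and 89 genes passed in Snf5-/-, Brg1-/- and between the mutants, with a 2-fold change as well 544, 1128 and 136, and with all probe sets 2977 in Snf5-/- and 6675 in Brg1-/-. These numbers are of genes changed in Snf5-/- against wild type, genes changed in Brg1-/- against wild type, genes different between Brg1-/- and Snf5-/- and genes changed in both Snf5-/- and Brg1-/-. The counts with all probe sets are the exception, being of probe sets, with or without a single gene symbol, and not of genes. By camera with an estimated correlation 0, 0 and 0 lists passed, and by fry 6, 14 and 0, against 13, 8 and 16 by camera at its preset correlation and 2906, 4687 and 1798 genes at an unadjusted p under 0.05.

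Without 1 array, genes changed in Snf5-/- against wild type numbered 920 to 1814, genes changed in Brg1-/- against wild type 2763 to 4166, genes different between Brg1-/- and Snf5-/- 128 to 756 and genes changed in both Snf5-/- and Brg1-/- 768 to 1638, lists 8 to 15, 8 to 13 and 14 to 22, and the correlation was 0.73 to 0.79 (jackknife SE 0.058).

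Some single genes changed sign. With quantile normalization the log2 change became 0.0080 for Smarca2 in Snf5-/-, and in Brg1-/- 0.45 for Smarcb1, 0.048 for Smarca2, 0.018 for B2m, 0.046 for Macroh2a1, 0.28 for H1f2 and 0.013 for Igf2r, with 0.040 for Smarca2 between the mutants. With centring it was 0.0091 (Smarca2: genes changed in Snf5-/- against wild type), in Brg1-/- 0.33 for Smarcb1, 0.042 for Smarca2, 0.025 for B2m and 0.040 for H1f2, and 0.033 for Smarca2 between the mutants. With cyclic loess it was 0.39 for Smarcb1, 0.033 for Smarca2, 0.13 for B2m, 0.039 for Macroh2a1, 0.21 for H1f2 and 0.0054 for Igf2r in Brg1-/-, and 0.043 for Smarca2 between the mutants. The mean of probe sets gave -0.071 for Smarca4 in Snf5-/- and 0.10 for Smarca2 between the mutants, and removal of probe sets that may detect several transcripts -0.0092 (Lss: genes different between Brg1-/- and Snf5-/-). Array weights gave 0.00073 for Smarca2 in Snf5-/- and 0.062 for Smarcb1 in Brg1-/-. Leaving out 1 array gave -0.49 to 0.032 for Smarca2 in Snf5-/- and -0.16 to 0.045 for Smarcb1 in Brg1-/-, each positive without wild type replicate 1, -0.13 to 0.24 for Smarca4 in Snf5-/-, negative without wild type replicate 2 or 3 or Snf5-/- replicate 1 or 3, and -0.28 to 0.13 for Smarca2 between the mutants, positive without Snf5-/- replicate 3. Over all named genes and alternatives, 3901 of 4293 values kept direction and side of the threshold, 315 no longer passed, 44 came to pass and 33 changed sign.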

Other observations

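The observations on genes and lists here were made only after their values were seen, and no test was planned for them. Arid1a, which encodes a DNA-binding subunit of SWI/SNF, rose in both mutants, from 1177 ± 302 (SD, n = 3) in wild type to 2201 ± 363 (n = 3) in Snf5-/- and 1847 ± 102 (n = 4) in Brg1-/-. Its log2 change was 1.24 ± 0.09 (SE) in each, with adjusted p = 1.15e-05 and 2.66e-06, and leaving out any 1 array did not end either call. Fos, Egr1 and Egr2, immediate early transcription factor genes, rose by 1.35 ± 0.18, 1.37 ± 0.22 and 2.55 ± 0.26 in Snf5-/- and 2.59 ± 0.16, 1.71 ± 0.20 and 1.93 ± 0.24 in Brg1-/-, while Maff and Fosl1 fell by 1.58 ± 0.20 and 1.03 ± 0.16 in Snf5-/- and 1.48 ± 0.19 and 0.78 ± 0.15 in Brg1-/-. The immediate early list as a whole did not pass (adjusted p = 0.428 and 0.0830 on the deposited scale).

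Of 7 measured chondrocyte and osteoblast markers, 3 rose in Snf5-/- and 4 did not pass. The list passed on the deposited scale only (adjusted p = 0.0335, against 0.371 after quantile normalization and 0.463 with an estimated correlation). Col2a1, the main cartilage collagen, rose by 1.49 ± 0.33 (SE, log2), and Matn4 and Matn3, matrilins, by 1.85 ± 0.43 and 1.54 ± 0.43. Without wild type replicate 1 the deposited adjusted p was 0.0633 for Matn4 and 0.137 for Matn3, and Matn3 was also lost without wild type replicate 3 or Snf5-/- replicate 1 or 2. Of 19 measured Hox genes, 2 were higher and 6 lower in Brg1-/- on the deposited scale, and 2 higher and 0 lower after quantile normalization, and the list did not pass (adjusted p = 0.0543 and 0.390). The 2 that rose were the limb patterning genes Hoxd13 and Hoxd11, by 1.5 ± 0.27 and 1.52 ± 0.36, and Hoxd11 was lost without wild type replicate 2 (adjusted p = 0.129), wild type replicate 3 or Brg1-/- replicate 4. Of 8 measured epithelial and keratinocyte markers, 7 were lower in Brg1-/- on the deposited scale and 4 after quantile normalization. The list passed only on the latter (adjusted p = 0.00865, against 0.0624 on the deposited scale), with adjusted p = 0.348 with an estimated correlation. The members that fell included Perp at -2.41 ± 0.23, Cldn4, a tight junction claudin, at -2.15 ± 0.54 and Krt18, a keratin, at -1.67 ± 0.39.

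Sex-linked genes differed between arrays. Xist, expressed from the inactive X chromosome, measured 183 in wild type replicate 2 and between 1550.3 and 4477 in the other 9 arrays. Eif2s3y, a Y-linked gene, measured 290.2, 255 and 189 in the wild type arrays and between 49.6 and 149 in the mutant arrays. Uty and Kdm5d, also Y-linked, measured 143.9 to 206.5 and 68.9 to 102.9 in wild type and 40.6 to 143.1 and 9.3 to 48.6 in the mutants. On the deposited scale, where the wild type arrays were the brightest, every wild type array lay above every mutant array for all 3. On that scale wild type and Brg1-/- arrays did not overlap for 53.1% of all tested genes. Kdm5d lay at or below background in replicates 1 and 2 of both mutants. The order of the arrays after quantile normalization is not given for these genes. Sex was not separated from genotype. Ifi202b measured 239 in Brg1-/- replicate 1 and 2.0, 4.9 and 4.0 in the others, and Erdr1 measured 172 in Snf5-/- replicate 3 and 1221 and 1186 in the others. Of 7 erythroid markers on the array, 0 lay above background in all arrays.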
